A study of Mus musculus with 9 samples.

How the data were processed

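The values came from the deposited table, which gives CPM (read counts scaled to a library total of 1e+06) of 49671 mouse Ensembl gene IDs in 9 libraries of sorted microglia, 3 mice at each of 7, 30 and 90 days after controlled cortical impact. According to the study's protocol text, male C57BL/6 mice (CD45.2) received CD45.1 donor marrow at 8 weeks of age after busulfan and body irradiation with the head shielded, and were injured at 16 weeks. Viable microglia were sorted by a CD45.2 gate that leaves out CD45.1 cells derived from the donor marrow. RNA was extracted with a PicoPure kit, and QuantSeq 3' mRNA libraries were sequenced on a NextSeq 500 to a stated average of 20000000 reads per sample. Per the processing notes of the deposited data, the authors used bcl2fastq, STAR and HTSeq with the mm10 genome; tool versions, the annotation release and the strand setting are not given in the sources used here. The sources name no sequencing or sorting batch.

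Each column of the CPM table sums to 1e+06. Dividing each column by its smallest step, the CPM of 1 read, recovered whole reads for 100% of values within a tolerance of 1e-06, and these gave the depths of 7210985 to 12965926 reads counted to genes per library. Of the listed genes, 27178 were at 0 in every library. Genes with at least 1 CPM in at least 3 libraries were kept, 15041 in all, of which 649 have no symbol in the table. Gene positions came from GENCODE M21 on the mm10 (GRCm38) assembly, which holds 49326 of the IDs. Genes with close paralogs or pseudogenes include Naip2, Lyz2, the hemoglobin genes, major histocompatibility genes and ribosomal protein genes. Their reads may have been shared with the copies or dropped, which was not tested, and their levels are uncertain. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The p-values rest on the spread between the 9 mice. In limma each gene's own spread, with 6 residual degrees of freedom, is combined with a trend over the 15041 genes tested, with 28.4 prior degrees of freedom.

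Values were analysed as log2(CPM + 1), with a pseudocount of 1 CPM. R 4.3.3 and limma 3.58.1 (lmFit, eBayes with a mean trend) fitted 1 mean per time point over all 9 libraries, so that the 3 time points share an estimate of the spread. The 3 pairwise contrasts and a moderated F-test over the time points were tested, each two-sided with Benjamini-Hochberg adjustment over all 15041 genes and a threshold of 0.05. The tests, the gene lists and the rule for naming genes were fixed before the data were examined. In each pairwise comparison the rule named up to 12 largest rises and 12 largest falls among genes past the threshold whose 3 libraries at one time lay wholly above the other 3, leaving out predicted gene models. Where fewer than 5 passed in a direction, the 5 genes with the smallest p were named as short of the threshold. The rule added up to 4 members from each passing biology list, the most abundant member of each cell type or quality list, and in every case P2ry12, Tmem119, Cx3cr1, Apoe, Trem2 and Ptprc.

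The 33 gene lists were written from general knowledge. The biology lists covered homeostatic microglia, disease-associated microglia, type I interferon response, inflammatory cytokines and NF-kB targets, cell cycle, complement and its receptors, antigen presentation, lysosome and phagocytosis, cholesterol synthesis, lipid efflux and LXR targets, nuclear-encoded oxidative phosphorylation, glycolysis and hypoxia, unfolded protein response, oxidative stress and iron, p53 targets and senescence, alternative activation and repair, Alzheimer disease risk genes of microglia, and TGF-beta signalling. Quality lists covered immediate early and tissue dissociation genes, heat shock, cytoplasmic ribosomal proteins and mitochondrially encoded genes. Cell type lists covered monocytes, border-associated macrophages, neutrophils, T and NK cells, B cells, dendritic cells, red cells, neurons, astrocytes, oligodendrocytes, and endothelial cells and pericytes. Lists overlap, so that Apoe, Axl and Lpl count in more than 1. Each list was tested per contrast with camera at a preset correlation of 0.01, two-sided, with adjustment over all 99 tests, and again with an estimated correlation and with fry, which asks whether the members move on balance one way without comparing them with other genes. At the preset correlation 18, 16 and 10 lists passed for day 30 against day 7, day 90 against day 7 and day 90 against day 30. With the estimated correlation the interferon response list passed at day 30 and at day 90 against day 7, and no other list did. A list median with members at 0 reads in 1 time point was also taken with those members at a bound of 3 reads over the group; this applied to 15 medians and moved 0 of them.

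Alternatives were pseudocounts of 0.1 and 5 CPM, no filter on low values, a filter at 10 CPM, median-of-ratios scaling, quantile normalization, totals without mitochondrial and ribosomal protein genes, only the 2 time points compared, library weights, a robust spread, a block for replicate number, an added 2-fold limit, and leaving out each library in turn. Also run were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. After the data were seen, a fit with the mean levels of the neuronal and endothelial lists as covariates and a fit on reads thinned to the shallowest library were added. On the recovered reads edgeR called 0, 22 and 7 genes and DESeq2 called 34, 129 and 27 genes for day 30 against day 7, day 90 against day 7 and day 90 against day 30. The procedure was tested on simulated data with 200 changed genes of at least 10 CPM among 15041 in 5 simulations of the day 90 against day 7 contrast. It recovered 12.0% of 2-fold, 67.6% of 4-fold, 86.0% of 8-fold and 84.4% of 16-fold changes, with a mean of 6.2 false calls. It called 0 of 33 lists without simulated change, checked on day 30 against day 7 with adjustment over the 33 lists. The simulated genes varied independently of one another, so the list check cannot show how the preset correlation fares with correlated members. The estimated correlation of the disease-associated list was 0.41.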

Results

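Messenger RNA was measured in microglia, the resident macrophages of the brain, sorted from male mice at 7, 30 or 90 days after a controlled cortical impact, a model of traumatic brain injury. Each of the 3 time points had 3 mice with 1 library each, 9 libraries in all. The day 7 and day 30 libraries carried replicate numbers 2, 3 and 4, and the day 90 libraries carried numbers 1, 3 and 4. The mice had received CD45.1 donor marrow before injury, so that host microglia could be sorted as CD45.2 cells. The 3 time points were compared with one another, since libraries from uninjured or sham-operated mice were not analysed here.

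The libraries held 7210985 to 12965926 reads counted to genes. The day 7 libraries held 9830520, 7210985 and 11312874 reads in replicates 2, 3 and 4, and the day 30 libraries 12965926, 11150956 and 11414647 reads. The day 90 libraries held 11209396, 10538774 and 11824787 reads in replicates 1, 3 and 4. A count of 3 reads corresponded to between 0.231 and 0.416 CPM, read counts scaled to a library total of 1e+06. Between 14039 and 17334 genes had at least 1 read, the fewest in day 90 replicate 1. Libraries of the same time point correlated across genes with a Pearson r of 0.842 to 0.908, and genes are not independent replicates. Day 90 replicate 1 stood apart from the other libraries, with a median correlation of 0.837 with the rest against 0.866 to 0.887 for the others. It lay at 126.6 on the first principal component, which held 21.2% of the variance, while the other 8 libraries lay between -22.9 and -3.13.

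**Figure D1:**
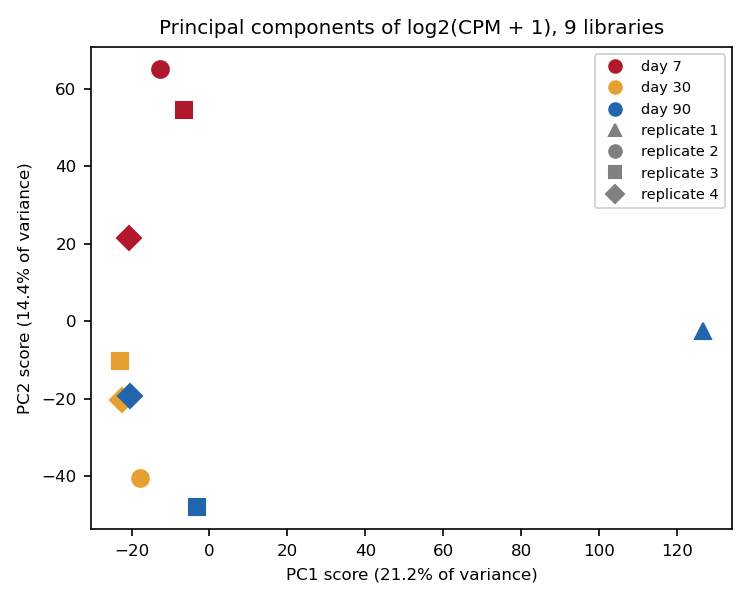
Position of each of the 9 libraries on the first and the second principal component of log2(CPM + 1), which hold 21.2% and 14.4% of the variance; colours give the day and marker shapes the replicate. Day 90 replicate 1 lies at 126.6 on the first component, and the other libraries lie between -22.9 and -3.13.

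The comparison of day 90 with day 7 addressed how microglia differ between the chronic and the acute phase of injury. The genes that fell to day 90 included markers of disease-associated microglia, a state of phagocytic, lipid-handling cells entered around damaged tissue. Among them were Spp1, which encodes the secreted matrix protein osteopontin, Gpnmb, a membrane glycoprotein of phagocytes, the lipase gene Lpl, the cystatin gene Cst7 and the growth factor gene Igf1. Genes induced by type I interferon, the antiviral cytokine, were lower as a group, with Bst2 and Irf7 past the threshold. The lipid carrier gene Apoe and the lysosomal genes Grn and Ctsz fell too. Genes that rose past the threshold included Sqstm1, which encodes the autophagy receptor p62, and the fructose transporter gene Slc2a5, a marker of homeostatic microglia.

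Of the 15041 genes tested with limma, 37 differed between day 90 and day 7 at an adjusted p under 0.05, 6 of them higher and 31 lower at day 90, while 523 genes were higher and 639 lower at an unadjusted p under 0.05. By chance, 752 genes in all would be expected at that unadjusted threshold. Spp1 (ENSMUSG00000029304, mm10 chromosome 5, 104435118 to 104441050) fell from 258 ± 93.8 CPM (SD, n = 3) to 8.51 ± 9.89 CPM, a log2 change of -5.55 ± 0.56 (SE, adjusted p = 9.04e-08). This call was lost with DESeq2 (adjusted p = 0.0525), with a robust spread (0.206) and without a filter on low values (0.256), while the adjusted p over all 25 alternatives ranged from 1.45e-23 to 0.256. The Spp1 change was -4.35 without day 90 replicate 1 and -6.52 without day 90 replicate 4. Gpnmb (chromosome 6, 49036546 to 49070929) fell from 261 ± 119.5 to 20.8 ± 14.6 CPM, with a log2 change of -3.71 ± 0.36. Lpl fell from 314 ± 123 to 55.4 ± 10.8 CPM, Cst7 from 171 ± 39.4 to 29.6 ± 12.3 CPM and Igf1 from 94.1 ± 17.96 to 8.29 ± 3.66 CPM. Apoe, which encodes the lipid carrier apolipoprotein E and is among the most abundant microglial transcripts, fell from 4362 ± 704 to 1720 ± 703 CPM, a log2 change of -1.41 ± 0.23 (adjusted p = 0.000695). Cd72, an inhibitory receptor gene, fell by 3.06 on the log2 scale, and Axl, a receptor for apoptotic cells, by 1.65. Among genes with little signal left at day 90, the macrophage survival factor gene Cd5l had 817 reads over the day 7 libraries and 0 at day 90, at least 322-fold lower. The iron-binding lipocalin gene Lcn2, a member of the neutrophil list, had 1193 reads at day 7 and 9 at day 90. Gpx3, a secreted peroxidase gene, and Cenpa, which encodes a centromere histone, fell by 3.80 and 3.56. The sulfatase gene Sulf2, the scavenger receptor gene Msr1 and the inhibitory receptor gene Cd300lf fell by 3.52, 3.02 and 2.53. Of these low-level genes, Cenpa lost its call without any of the 9 libraries (-3.03 to -3.89), Gpx3 without any of 6 (-3.18 to -4.08), Lcn2 without day 7 replicates 2 or 4 or day 90 replicate 3 (-3.90 to -4.41), Sulf2 without any day 7 library (-3.41 to -3.65), Msr1 without any day 7 library or day 90 replicate 3 (-2.76 to -3.17), and Cd300lf without day 7 replicates 2 or 3 (-2.54 and -2.40).

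**Figure D2:**
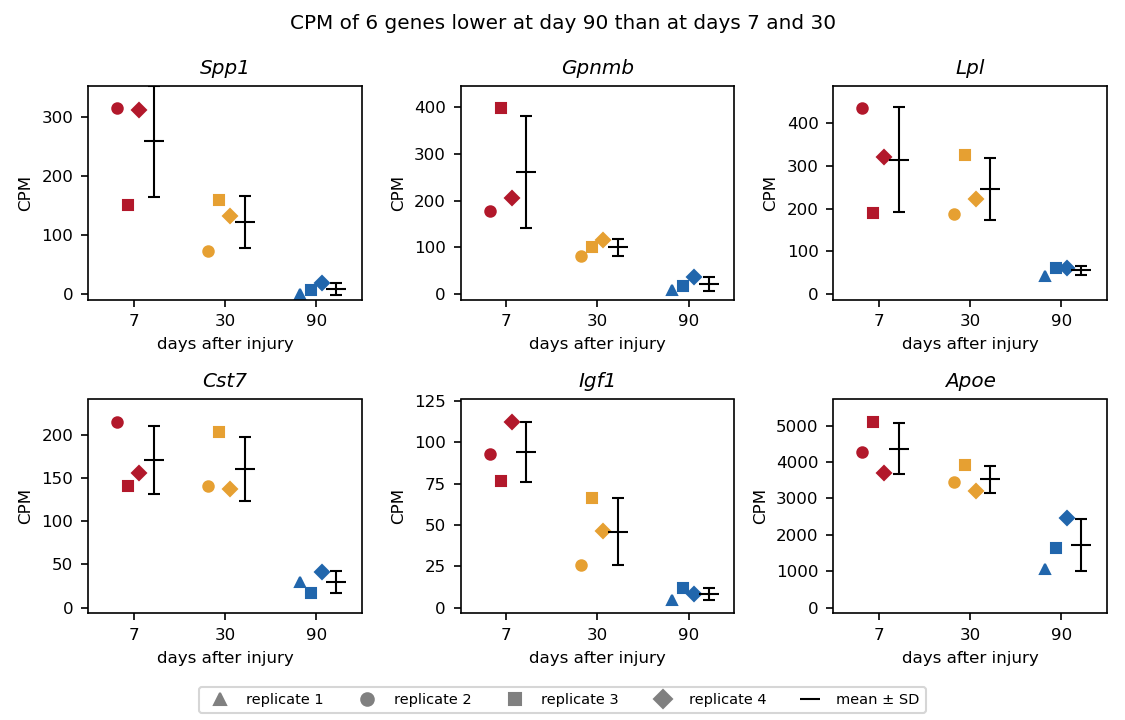
CPM of 6 genes in each library at 7, 30 and 90 days after injury, with the mean and SD of the 3 libraries per day beside the points; marker shapes give the replicate. Spp1 averages 258, 121 and 8.51 CPM at days 7, 30 and 90, and Apoe 4362, 3523 and 1720 CPM.

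The disease-associated microglia genes, fixed as a list of 32 tested members, had a median log2 change of -1.03 with 31 members lower at day 90 (camera adjusted p = 3.41e-50; adjusted p = 0.065 with an estimated correlation). Of these members, 15 fell past the threshold over all genes tested and 22 adjusted over the list alone. Their summed level was 25310 ± 1955 CPM at day 7 and 14257 ± 3018 CPM at day 90, with the lowest value, 10909 CPM, in day 90 replicate 1. The interferon response list of 37 members had a median of -1.17 with 36 members lower (adjusted p = 5.15e-20; adjusted p = 0.0216 with an estimated correlation). Its Bst2, which encodes the virus-tethering protein tetherin, fell from 303 ± 68.0 to 121 ± 43.4 CPM (adjusted p = 0.00488), and Irf7, the transcription factor that amplifies interferon production, fell from 66.2 ± 25.5 to 11.2 ± 0.611 CPM (adjusted p = 0.0207). These were the 2 interferon calls over all genes, and 15 members fell adjusted over the list alone. The lipid efflux list had a median of -0.29 (adjusted p = 3.63e-05; adjusted p = 0.133 with an estimated correlation), with Apoe, Lpl and the lipid droplet gene Plin2 as its 3 calls over all genes and 5 adjusted over the list alone. The lysosome list had a median of -0.30 (adjusted p = 1.58e-08; adjusted p = 0.219 with an estimated correlation). Its 6 falls over all genes included Axl, Msr1, the progranulin gene Grn and the cathepsin gene Ctsz, and 11 members fell and 1 rose adjusted over the list alone. Bst2 lost its call without day 7 replicate 3 (-1.18) or day 90 replicate 3 (-1.20), Irf7 without day 7 replicates 3 or 4 or day 90 replicates 3 or 4 (-2.19 to -2.40), and Ctsz without any of 6 libraries (-0.81 to -1.004).

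The homeostatic microglia list of 27 members had a median of +0.19 at day 90 against day 7 (adjusted p = 0.0162; adjusted p = 0.59 with an estimated correlation). Slc2a5 rose from 216 ± 7.92 to 402 ± 47.8 CPM (adjusted p = 0.0408), the 1 call of this list over all genes, against 2 rises and 1 fall adjusted over the list alone. The purine receptor gene P2ry12 stood at 933 ± 145 and 1046 ± 63.1 CPM, and the microglia-specific gene Tmem119 at 840.5 ± 118 and 1022 ± 198 CPM. Cx3cr1, the fractalkine receptor gene, stood at 4577 ± 876 and 7151 ± 2066 CPM, Trem2, a lipid-sensing receptor gene, at 1182 ± 62.4 and 1125 ± 253 CPM, and Ptprc, which encodes CD45, at 337 ± 36.5 and 319.8 ± 37.1 CPM. These 5 genes did not pass the threshold. Sqstm1 rose from 238 ± 18.9 to 507 ± 122 CPM (adjusted p = 0.0108). Naip2, an inflammasome sensor gene with close paralogs that may share reads with it, rose by 1.88 on the log2 scale (adjusted p = 0.0147). Limd2 and Trim47 rose by 1.21 and 1.18. The homeostatic call was lost in 5 of the 23 alternatives other than the estimated correlation and fry. These included the fits without day 7 replicate 3 (median +0.15), day 90 replicate 3 (+0.15) or day 90 replicate 4 (+0.12). The homeostatic median was +0.30 without day 90 replicate 1, and Slc2a5 lost its call without any of 7 libraries (+0.84 to +0.91). The call was also lost for Sqstm1 without day 7 replicates 2 or 4 or day 90 replicates 3 or 4 (+0.89 to +1.05), for Naip2 without day 7 replicate 2 (+1.16) or day 90 replicates 3 or 4 (+1.71 and +1.87), for Limd2 without any day 7 library or day 90 replicates 3 or 4 (+1.04 to +1.23) and for Trim47 without any of 5 libraries (+0.93 to +1.26).

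Markers of other cells and signs of tissue handling moved over the same interval. The monocyte markers had a median of -0.88 between day 7 and day 90 (adjusted p = 0.00198; adjusted p = 0.232 with an estimated correlation), and their summed level went from 323 ± 28.6 to 190.2 ± 50.2 CPM. The monocyte median was -1.35 without day 7 replicate 4 and -1.51 without day 90 replicate 4. The median of the endothelial and pericyte markers was -0.36 (adjusted p = 0.000865; adjusted p = 0.498 with an estimated correlation), and the highest day 90 level, 4908 CPM, was in replicate 1. Their call was lost without day 7 replicate 3 (-0.25) or day 90 replicate 4 (-0.17), and the median was -0.76 without day 90 replicate 1 and -0.61 without day 7 replicate 4. The neutrophil markers had a median of -0.97 (adjusted p = 0.00414, and adjusted p = 0.401 with an estimated correlation) and lost the call without day 7 replicate 3 (-0.29) or day 90 replicate 3 (-0.72), with medians of -1.99 without day 7 replicate 2 and -1.52 without day 90 replicate 4. Lcn2 was the 1 neutrophil marker past the threshold over all genes. Immediate early genes, which respond within minutes to stimulation and to tissue dissociation, had a median of +0.37 (adjusted p = 4.58e-08; adjusted p = 0.232 with an estimated correlation), with 6 members risen and 1 fallen adjusted over the list alone. Heat shock genes, which encode chaperones, had a median of +0.62 (adjusted p = 0.000308; adjusted p = 0.417 with an estimated correlation), a call lost without day 7 replicate 3 (+0.23) or day 90 replicate 3 (+0.15), with +1.05 without day 7 replicate 2 and +0.39 without day 7 replicate 4. The cytoplasmic ribosomal protein genes, many of which may share reads with pseudogenes, had a median of -0.31 (adjusted p = 2.61e-05, and adjusted p = 0.065 with an estimated correlation).

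Leaving out 1 library at a time gave between 18 and 62 genes for day 90 against day 7, with 18 without day 7 replicate 2, 24 without day 7 replicate 3, day 7 replicate 4 or day 90 replicate 3, and 62 without day 90 replicate 1, while 1 gene passed without a filter on low values. The lipid efflux median was -0.10 without day 7 replicate 3 or day 90 replicate 4, -0.58 without day 7 replicate 4 and -0.51 without day 90 replicate 1, and the lysosome median was -0.17 without day 90 replicate 1.

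**Figure D3:**
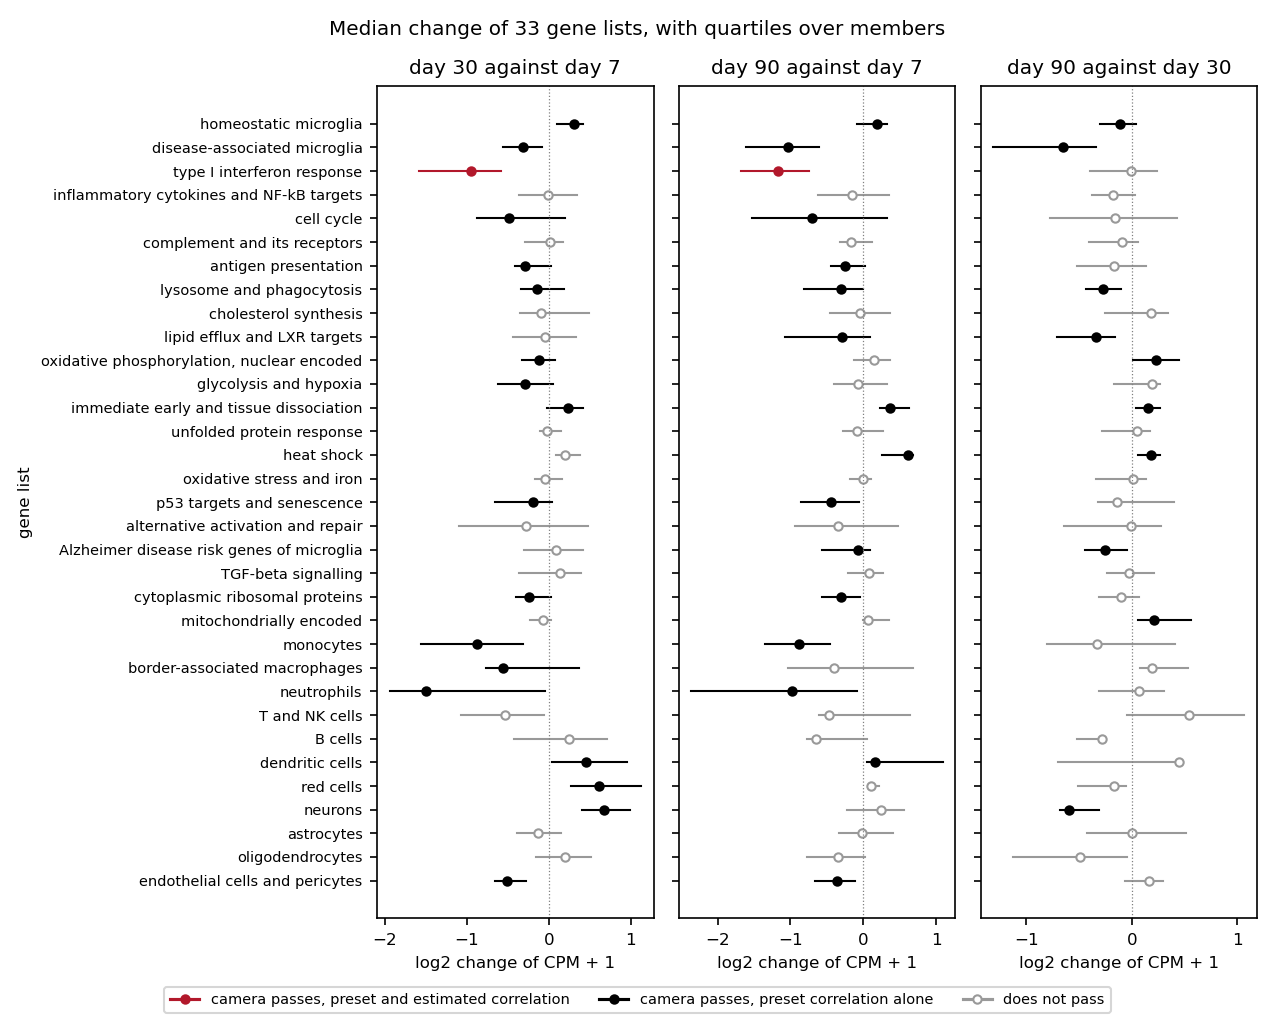
Median log2 change of CPM + 1 of 33 gene lists in the 3 comparisons, with lines from the lower to the upper quartile of the members; red marks lists that pass camera with both a preset and an estimated correlation, black with the preset correlation alone, and open grey neither. The interferon list passes both ways at day 30 and day 90 against day 7, with medians of -0.94 and -1.17.

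The comparison of day 90 with day 30 addressed what still changes after the subacute phase. The genes that fell late again came from the disease-associated program: Spp1, Cst7, Lpl, Gpnmb, Igf1, Axl and Apoe, together with Cd72, whose product restrains immune receptor signalling. The interferon genes, which respond to antiviral cytokine, stood at much the same level at both times. Lpl and Apoe, which release and carry lipid, are also the 2 members of the lipid efflux list that fell past the threshold over this interval. Of its 18 members, 15 were lower at day 90.

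With limma, 8 of the 15041 genes differed between day 90 and day 30, all 8 lower at day 90. Cst7 fell from 160.3 ± 37.3 to 29.6 ± 12.3 CPM (log2 change -2.46 ± 0.30, adjusted p = 1.56e-05), Spp1 from 121 ± 44.1 to 8.51 ± 9.89 CPM (-4.46 ± 0.56, adjusted p = 1.75e-05) and Lpl from 245 ± 72.5 to 55.4 ± 10.8 CPM (-2.10 ± 0.27, adjusted p = 2.04e-05). Gpnmb, Igf1, Cd72 and Axl fell by 2.41, 2.32, 2.05 and 1.51 on the log2 scale. Apoe fell from 3523 ± 366 to 1720 ± 703 CPM (-1.11 ± 0.23, adjusted p = 0.0446). The Spp1 call was lost with edgeR (adjusted p = 0.106), DESeq2 (0.512), a robust spread (0.738) and no filter on low values (0.832), in a range of 5.27e-08 to 0.832 over 25 alternatives, and the change was -3.27 without day 90 replicate 1 and -5.44 without day 90 replicate 4. With neuronal and endothelial marker levels as covariates, Gpnmb (-1.37), Igf1 (-2.12), Cd72 (-1.34), Axl (-1.56) and Apoe (-0.81) lost their calls. Without a filter on low values limma called 0 genes, against 757 unadjusted with the filter, 7 with edgeR and 27 with DESeq2. The unadjusted count was close to the 752 genes expected by chance. Of the genes higher at day 90, the transcription factor gene Klf4 had the smallest p. Klf4, also a member of the immediate early and tissue dissociation list, stood at 502 ± 47.3 CPM on day 30 and 896 ± 146 CPM on day 90 (adjusted p = 0.144). It was followed by Kl, Cbx7, Pik3c2a and Stk39, with log2 changes of +1.32, +1.30, +1.19 and +1.40, all short of the threshold.

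All 32 disease-associated members were lower at day 90 than at day 30, with a median of -0.65 (adjusted p = 3.61e-35; adjusted p = 0.128 with an estimated correlation); 7 fell over all genes tested and 17 adjusted over the list alone. The lipid efflux list had a median of -0.34 (adjusted p = 0.000358; adjusted p = 0.187 with an estimated correlation), with Apoe and Lpl as its 2 calls both over all genes and adjusted over the list alone. The median of the lysosome list was -0.27 (adjusted p = 2.48e-05; adjusted p = 0.298 with an estimated correlation), with Axl as its 1 call over all genes and 2 adjusted over the list alone. The interferon list had a median of -0.003 (adjusted p = 0.997, camera direction higher), the sign of which turned positive under median-of-ratios scaling, quantile normalization and totals without mitochondrial and ribosomal protein genes. Between these days the monocyte markers had a median of -0.33 (adjusted p = 0.834, camera direction higher, and a positive median under quantile normalization) and the endothelial markers one of +0.16 (adjusted p = 0.176). The neuronal markers, transcripts of cells outside the sort gate, had a median of -0.59 (adjusted p = 5.35e-05; adjusted p = 0.232 with an estimated correlation), and 3 of 17 members fell adjusted over the list alone.

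Single libraries moved the count for day 90 against day 30 from 8 to 5 without day 30 replicate 2, 4 without day 30 replicate 3, 5 without day 30 replicate 4 and 18 without day 90 replicate 4; Apoe kept its call in 9 of 25 alternatives and lost it without 7 of the 9 libraries (-0.81 to -1.18), Cd72 without day 30 replicates 2, 3 or 4 or day 90 replicate 3 (-1.74 to -2.17), Axl without day 30 replicates 2 or 3 or day 90 replicate 3 (-1.32 to -1.43), and Igf1 without day 30 replicates 3 or 4 (-2.01 to -2.27). Without day 90 replicate 1 the lysosome median was -0.08 and the neuronal median -0.32, and without day 30 replicate 4 the neuronal median was -0.35.

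The comparison of day 30 with day 7 addressed the passage from the acute to the subacute phase. Interferon-induced genes were lower at day 30 as a group, although with limma single members such as Irf7, Bst2 and the antiviral genes Slfn5 and Rtp4 did not pass over all genes, while 21 members had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 2. Homeostatic genes mark surveying microglia, and disease-associated genes mark phagocytic ones. The homeostatic list was higher and the disease-associated list lower with a preset correlation alone (adjusted p = 0.298 and adjusted p = 0.375 with an estimated correlation). With limma and edgeR 0 members of either list passed, against 7 homeostatic and 8 disease-associated members unadjusted with limma and 2 and 1 members with DESeq2.

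With limma, 0 of 15041 genes passed for day 30 against day 7, while 939 genes had an unadjusted p under 0.05, 536 of them higher at day 30, where 752 would be expected by chance. The edgeR fit on recovered reads also called 0 genes and DESeq2 called 34. Naip2 had the smallest adjusted p (0.0534), with 31.9 ± 21.5 CPM at day 7 and 115 ± 12.4 CPM at day 30. Hpcal4, which encodes a neuronal calcium sensor, had 0 reads at day 7 and 542 at day 30, at least 144-fold higher (adjusted p = 0.255). Rab6b, Limk1 and the synaptic vesicle gene Syt1 followed, with log2 changes of +1.04, +1.76 and +1.65. On the lower side, Lgals3bp, a secreted galectin-binding protein gene, went from 608 ± 33.02 to 305 ± 20.6 CPM (adjusted p = 0.111), and Lcn2, Plin2, Bst2 and Cd5l had log2 changes of -4.25, -1.32, -1.11 and -3.58.

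The interferon list had a median of -0.94 at day 30 with 35 of 37 members lower (adjusted p = 2.68e-23; adjusted p = 0.0216 with an estimated correlation), and 17 members fell adjusted over the list alone. Its summed level went from 2221 ± 231 to 1118 ± 65.9 CPM and stood at 1135 ± 210.0 CPM on day 90. Irf7 was at 66.2 ± 25.5 CPM on day 7 and 16.4 ± 9.03 CPM on day 30, Slfn5 at 137 ± 39.5 and 49.95 ± 16.5 CPM, and Rtp4 at 56.9 ± 11.0 and 12.8 ± 10.3 CPM, each with an adjusted p of 0.362. The homeostatic list had a median of +0.30 with 23 of 27 members higher (adjusted p = 1.23e-06; adjusted p = 0.298 with an estimated correlation), and 2 rose adjusted over the list alone. P2ry13 stood at 1091 ± 94.1 CPM on day 7 and 1735 ± 61.7 CPM on day 30 (adjusted p = 0.388). Tmem119 stood at 840.5 ± 118 and 1199 ± 93.1 CPM, P2ry12 at 933 ± 145 and 1291 ± 317 CPM, and Golm1 at 668 ± 126 and 949 ± 184 CPM. The disease-associated list had a median of -0.31 (adjusted p = 1.73e-07; adjusted p = 0.375 with an estimated correlation), and 2 members fell adjusted over the list alone. Apoe stood at 4362 ± 704 and 3523 ± 366 CPM (adjusted p = 0.88).

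Between day 7 and day 30 the neuronal markers had a median of +0.67 with 16 of 17 members higher (adjusted p = 2.89e-07; adjusted p = 0.187 with an estimated correlation). Their most abundant member, the noncoding RNA gene Meg3, stood at 945 ± 79.5 and 1792 ± 681 CPM. The median of the endothelial markers was -0.51 with all 15 members lower (adjusted p = 2.89e-07; adjusted p = 0.315 with an estimated correlation), and that of the monocyte markers -0.88 with 11 of 13 lower (adjusted p = 0.000256; adjusted p = 0.199 with an estimated correlation). Fn1, the fibronectin gene and the most abundant of the monocyte markers, stood at 205 ± 2.40 CPM on day 7 and 113 ± 21.1 CPM on day 30. The ribosomal protein genes had a median of -0.24 (adjusted p = 5.35e-05; adjusted p = 0.065 with an estimated correlation).

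Leaving out day 90 replicate 1 gave 8 genes for day 30 against day 7, and the count over all such omissions was 0 to 8; the disease-associated median was -0.17 without day 7 replicate 2. The monocyte call was lost with neuronal and endothelial marker levels as covariates (median -0.30), and the monocyte median was -1.40 without day 7 replicate 4.

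**Figure D4:**
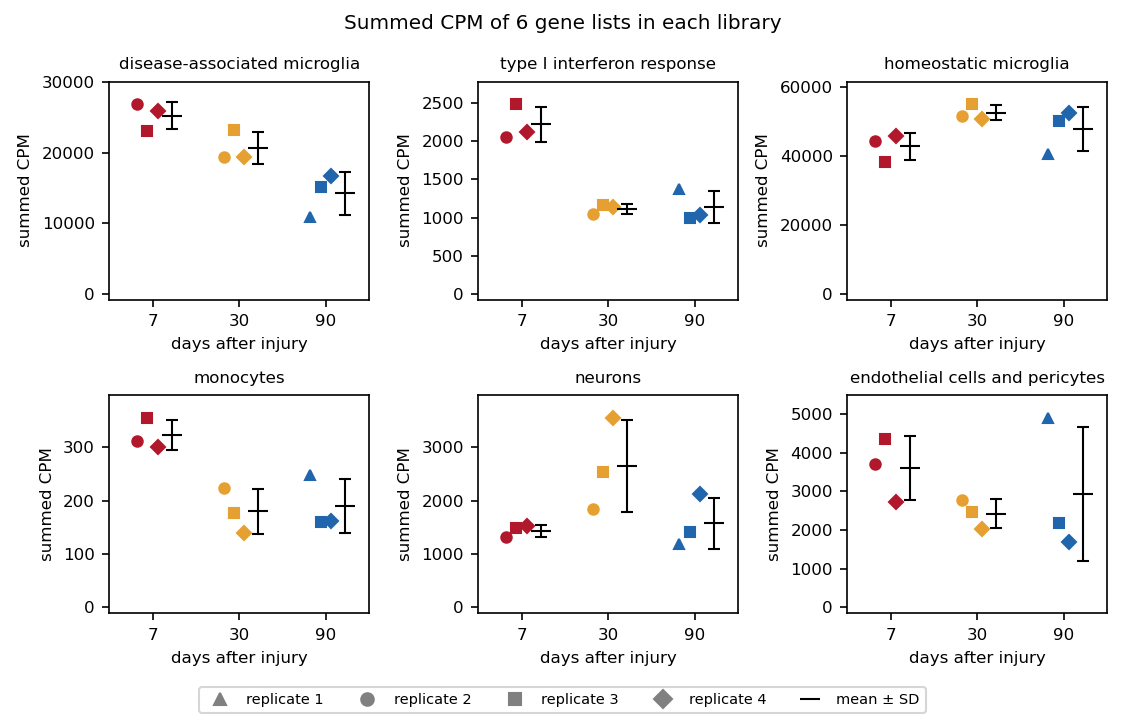
Summed CPM of 6 gene lists in each library at 7, 30 and 90 days, with the mean and SD of the 3 libraries per day beside the points; marker shapes give the replicate. The interferon response genes sum to 2221, 1118 and 1135 CPM at days 7, 30 and 90, and the disease-associated genes to 25310, 20702 and 14257 CPM.

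A test of any change over the 3 time points asked which genes vary with time at all. Most of the genes it called had their highest mean at day 7 and their lowest at day 90, as did Spp1, Gpnmb and Igf1. This class ranks means alone and does not give 1 shared course. Cst7 and Axl had log2 changes of -0.09 and -0.14 from day 7 to day 30, against -2.46 and -1.51 from day 30 to day 90. Bst2 and Irf7 had -1.11 and -2.02 over the first interval, against -0.24 and -0.36 over the second. Lmnb1 encodes a protein of the nuclear lamina. Its mean was lowest at day 90 and highest at day 30, but above day 7 only by a margin within the spread. A separate course was thus not shown for Lmnb1.

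The limma F-test called 26 of 15041 genes, against 1034 at an unadjusted p under 0.05, and 22 of the 26 were highest at day 7 and lowest at day 90. The remaining 4 genes were singled out after their values were seen. Naip2 was highest at day 30 and lowest at day 7, and Sqstm1 and Limd2 were highest at day 90 and lowest at day 7. For Naip2, Sqstm1 and Limd2 the levels at days 30 and 90 were not told apart (limma adjusted p = 0.98, 0.955 and 0.959). Lmnb1 stood at 161 ± 44.8, 177 ± 23.6 and 71.5 ± 36.6 CPM on days 7, 30 and 90 (F-test adjusted p = 0.036). Its levels at days 7 and 30 were not told apart (limma log2 change +0.16 ± 0.31, adjusted p = 0.981). The share of genes whose 3 libraries at one time lay wholly above the 3 at the other was 12.6% for day 30 against day 7, 11.7% for day 90 against day 7 and 9.93% for day 90 against day 30, where chance gives 10%. Leaving out 1 library gave 11 genes without day 7 replicate 2, 15 without day 7 replicate 3, 13 without day 7 replicate 4 and 52 without day 90 replicate 1. Without a filter on low values limma called 0, against 1034 unadjusted with the filter, 16 with edgeR and 55 with DESeq2.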

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

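The fall of Gpnmb, Lpl, Cst7, Igf1, Cd72, Apoe, Axl, Grn and Plin2 from day 7 to day 90 kept its call in 24 of 25 alternatives each, the exception being no filter on low values. The lists of disease-associated genes (all 3 comparisons), interferon genes (against day 7) and lipid efflux genes (day 90 against either day) kept their preset-correlation call in all 23 alternatives other than the estimated correlation and fry. For every change given here without a cause, the cause was not tested.

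Genes called for day 30 against day 7 (0 with limma, 939 unadjusted, 0 with edgeR) numbered 3 with a pseudocount of 5 CPM, 2 with quantile normalization, 3 with library weights, 10 with a replicate block, 34 with DESeq2, 5 with neuronal and endothelial covariates and 1 with thinned reads. For day 90 against day 7 (37), the count was 1 without a filter, 18 with only the 2 time points compared, 22 with edgeR, 129 with DESeq2 and 144 with the covariates. The main calls were shared by 21 of the edgeR and 36 of the DESeq2 calls. For day 90 against day 30 (8), it was 0 without a filter (limma, against 757 unadjusted with the filter, 7 with edgeR and 27 with DESeq2), 5 with only the 2 time points compared, 27 with DESeq2 and 5 with the covariates, 3 of them shared with the main calls. In each pairwise comparison 752 genes would be expected by chance at an unadjusted p under 0.05. The F-test (26) called 15 genes with a pseudocount of 0.1 CPM, 0 without a filter (1034 unadjusted with the filter), 40 with library weights, 16 with edgeR, 55 with DESeq2, 99 with the covariates, and 39 with the replicate block. The loss without a filter goes with the prior degrees of freedom, which fell from 28.4 over 15041 genes to 2.96 over 22493.

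Leaving out 1 library gave 0 to 8 genes for day 30 against day 7, 18 to 62 for day 90 against day 7, 4 to 18 for day 90 against day 30 and 11 to 52 in the F-test. Passing lists ranged from 9 to 19, 12 to 18 and 7 to 13 in the 3 pairwise comparisons in that order. With an estimated correlation 1, 1 and 0 lists passed (camera; 10 with the preset correlation for the last), with fry 2, 5 and 0, and with the covariates 9 passed for day 30 against day 7.

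The oxidative phosphorylation median for day 30 against day 7 was +0.0196 with the covariates, and the heat shock median for day 90 against day 30 was -0.13 with the covariates and -0.21 without day 90 replicate 3, in a range of -0.21 to +0.41 over the omission of single libraries. Medians of lists that had lost their call also changed sign, for Alzheimer disease risk genes at day 90 against day 7 (+0.02 without day 90 replicate 1), dendritic cell genes there (-0.07 without day 90 replicate 4) and oxidative phosphorylation at day 90 against day 30 (-0.02 with the replicate block). Depth limits genes near the floor of 0.231 to 0.416 CPM, and thinning all libraries to the shallowest gave 1, 36 and 9 genes.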

Other observations

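Of the tests of explanations given here, those that leave out day 90 replicate 1 or day 30 replicate 4 and those that set one list against another (dilution by other cells, loss of monocyte RNA, share of microglia) were chosen after the result was seen, and the fits with covariates and with thinned reads were added after the data were seen.

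Cell cycle genes, which mark dividing cells, had a median of -0.49 at day 30 against day 7 (adjusted p = 0.0412; adjusted p = 0.541 with an estimated correlation) and of -0.71 at day 90 (adjusted p = 0.0162; adjusted p = 0.437 with an estimated correlation). Of the 23 alternatives other than the estimated correlation and fry, the first call was lost in 8 and the second in 6. The losses of the first included the fits without day 7 replicate 4 (-0.24), day 30 replicate 2 (-0.29) or day 30 replicate 4 (-0.26). Those of the second included the fits without day 7 replicate 4 (-0.38) or day 90 replicate 1 (-0.50). Antigen presentation genes, which load peptides for T cells, had medians of -0.29 at day 30 (adjusted p = 0.0239; adjusted p = 0.245 with an estimated correlation) and -0.25 at day 90 (adjusted p = 0.00827; adjusted p = 0.219 with an estimated correlation) against day 7. The cell cycle and antigen presentation lists had no member past the threshold at day 90 over all genes (0 with limma and edgeR, 9 and 3 unadjusted, 0 and 2 with DESeq2), and 3 antigen presentation genes fell adjusted over the list alone. The antigen presentation calls were lost without day 7 replicate 4 (-0.21 at both days), at day 30 also without day 30 replicate 3 (-0.28) or 4 (-0.15), and at day 90 without day 90 replicate 1 (-0.14), with day 90 medians of -0.37 without day 7 replicate 3 and -0.41 without day 90 replicate 4. The p53 and senescence list had medians of -0.20 at day 30 (adjusted p = 0.0178; adjusted p = 0.315 with an estimated correlation) and -0.45 at day 90 (adjusted p = 0.0125; adjusted p = 0.298 with an estimated correlation) against day 7. It lost the day 30 call without day 7 replicate 4 (-0.15) or day 30 replicate 4 (-0.16), with medians of -0.40 to -0.44 without day 7 replicate 3 or day 30 replicates 2 or 3, and the day 90 call without day 7 replicate 4 (-0.30) or day 90 replicate 1 (-0.36). The Alzheimer disease risk genes had medians of -0.08 at day 90 against day 7 (adjusted p = 0.019; adjusted p = 0.298 with an estimated correlation), with Apoe and Grn falling over all genes and 3 members adjusted over the list alone, and of -0.25 at day 90 against day 30 (adjusted p = 0.00407; adjusted p = 0.232 with an estimated correlation). Without day 90 replicate 1 both calls were lost, with medians of +0.02 and -0.24, and the first median was between -0.14 and -0.01 without day 7 replicate 3 or day 90 replicates 3 or 4.

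Genes of oxidative phosphorylation, the respiratory chain, had medians of -0.12 at day 30 against day 7 (adjusted p = 0.0134; adjusted p = 0.696 with an estimated correlation) and +0.23 at day 90 against day 30 (adjusted p = 3.19e-06; adjusted p = 0.437 with an estimated correlation). The first call was lost without day 7 replicate 3 or day 30 replicate 4 (-0.01 each), with medians of -0.20 without day 7 replicate 4 and -0.26 without day 30 replicate 3, and the second was lost without day 90 replicate 1 (+0.03) and stood at +0.38 without day 30 replicate 3. Mitochondrially encoded genes had a median of +0.21 in the latter comparison (adjusted p = 0.0161; adjusted p = 0.437 with an estimated correlation), lost without day 30 replicate 4 (+0.09) or day 90 replicate 1 (+0.02) and at +0.34 without day 90 replicate 3. Genes of glycolysis and hypoxia had a median of -0.29 at day 30 against day 7 (adjusted p = 0.0178; adjusted p = 0.204 with an estimated correlation), a call lost without day 7 replicate 4 (-0.29) or day 30 replicate 4 (-0.27). Heat shock genes had a median of +0.19 at day 90 against day 30 (adjusted p = 0.0412; adjusted p = 0.674 with an estimated correlation), which turned to -0.21 without day 90 replicate 3. The call was lost without day 7 replicate 4 (+0.19) or day 30 replicate 2 (+0.11), with +0.36 without day 30 replicate 3 and +0.41 without day 90 replicate 1. Immediate early genes had medians of +0.24 at day 30 against day 7 (adjusted p = 0.00434; adjusted p = 0.446 with an estimated correlation), lost without day 7 replicate 3 (+0.07) or day 30 replicate 4 (+0.20), and +0.15 at day 90 against day 30 (adjusted p = 0.00285; adjusted p = 0.437 with an estimated correlation), lost without day 90 replicate 3 (+0.005) and at +0.29 without day 90 replicate 1. Lysosome genes had a median of -0.14 at day 30 against day 7 (adjusted p = 0.0276; adjusted p = 0.561 with an estimated correlation), lost without day 7 replicate 2 (-0.09) or 4 (-0.14) or day 30 replicate 2 (-0.17) or 4 (-0.10), and at -0.23 without day 7 replicate 3. Homeostatic genes had a median of -0.11 at day 90 against day 30 (adjusted p = 0.0412; adjusted p = 0.674 with an estimated correlation), a call lost without any of 5 libraries (-0.04 to -0.14).

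Among cell type markers, border-associated macrophage genes had a median of -0.56 at day 30 against day 7 (adjusted p = 0.0162; adjusted p = 0.322 with an estimated correlation), lost without day 7 replicate 2 (-0.40) or 4 (-0.39) or day 30 replicate 4 (-0.37). The neutrophil median in that comparison was -1.50 (adjusted p = 0.00147; adjusted p = 0.351 with an estimated correlation), lost without day 7 replicate 3 (-0.26), and ranged from -2.77 without day 7 replicate 2 and -2.30 without day 30 replicate 4 to -0.99 and -0.74 without day 30 replicates 2 and 3. Red cell genes had a median of +0.61 (adjusted p = 0.0159; adjusted p = 0.315 with an estimated correlation), lost without day 7 replicate 2 (+0.37) or day 30 replicate 2 (+0.59). Dendritic cell genes had medians of +0.45 at day 30 (adjusted p = 0.0423; adjusted p = 0.245 with an estimated correlation) and +0.16 at day 90 (adjusted p = 0.042; adjusted p = 0.245 with an estimated correlation) against day 7. Each dendritic call was lost without any of 4 libraries, with values of +0.38 to +0.77 at day 30 and -0.07 (without day 90 replicate 4) to +0.39 at day 90, and ranged over all omissions from +0.27 to +0.90 and from -0.07 to +0.56. T and NK cell genes had adjusted p values of 0.0671, 0.94 and 0.0782 at day 30 against day 7, day 90 against day 7 and day 90 against day 30, B cell genes 0.683, 0.504 and 0.176, astrocyte genes 0.504, 0.983 and 0.505, and oligodendrocyte genes 0.776, 0.405 and 0.172.

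Several biology lists passed in no comparison, given in the same order. The adjusted p values were 0.954, 0.12 and 0.0811 for inflammatory cytokines and NF-kB targets, and 0.504, 0.0977 and 0.295 for complement. They were 0.995, 0.729 and 0.702 for cholesterol synthesis, 0.94, 0.504 and 0.504 for the unfolded protein response, and 0.553, 0.444 and 0.81 for oxidative stress and iron. For alternative activation and repair they were 0.0533, 0.1 and 0.94, with Igf1 and Msr1 falling over all genes at day 90 against day 7 and 3 members adjusted over the list alone, and for TGF-beta signalling 0.444, 0.313 and 0.83. The median differs in sign from the mean, the camera direction or both for complement at day 30 against day 7 (+0.02), for cholesterol synthesis against day 7 (-0.10 and -0.04), for the unfolded protein response (-0.02, -0.08 and +0.05), for Alzheimer disease risk genes at day 30 (+0.09), for oxidative stress at day 90 against day 30 (+0.01) and for TGF-beta signalling in that comparison (-0.03).

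A first hypothesis, beside mouse age, time since transplant and any sequencing batch, which go with time and were not tested, is that the fall of disease-associated genes to day 90 took place within microglia. Without day 90 replicate 1 the list median was -0.88 (camera adjusted p = 7.35e-36). With neuronal and endothelial marker levels as covariates it was -1.25 (camera adjusted p = 2.85e-70). Both p-values were computed at the preset correlation alone, and on all 9 libraries the list did not pass with an estimated correlation (adjusted p = 0.065). The size of the median change from day 7 was thus not lost without that library or with those markers in the fit. For day 90 against day 30 the list median was -0.67 with the covariates, and 5 of the 8 genes called there lost their calls, Axl (-1.56) and Igf1 (-2.12) at about the change they had without them (-1.51 and -2.32), and Gpnmb (-1.37), Cd72 (-1.34) and Apoe (-0.81) at smaller changes than without them (-2.41, -2.05 and -1.11). Dilution by RNA of other cells would lower homeostatic genes alike, whereas their lower quartile was -0.0834 against an upper quartile of -0.61 for the disease-associated genes. Loss of monocyte-derived RNA may contribute and stays open, although the CD45.2 gate leaves out donor-marrow cells: the monocyte median from day 7 to day 90 was -0.88, and between day 30 and day 90 the summed monocyte level differed by 9.92 CPM with a spread of 65.4 CPM, with Fn1, its most abundant gene, at 113 and 116 CPM. Loss of border-associated macrophage RNA was not tested. From day 7 to day 90 those markers had a median of -0.41 with 8 of 12 lower (camera adjusted p = 0.259). From day 30 to day 90 their median was +0.19 (camera adjusted p = 0.295).

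A second hypothesis is that interferon signalling in microglia subsided between day 7 and day 30. With the neuronal and endothelial covariates the list median was -0.95 (camera adjusted p = 5.97e-14 at the preset correlation). Neither covariate overlapped between the 2 days. The highest neuronal mean log2 level at day 7 was 4.50 and the lowest at day 30 was 4.78. The lowest endothelial level at day 7 was 6.51 and the highest at day 30 was 6.50. The fit therefore cannot exclude RNA of those cells. Loss of monocyte RNA could also lower these genes, and it stays open, since the monocyte median was -0.88 over the same interval, with Fn1 at 205 and 113 CPM. The border-associated macrophage median was -0.56 over that interval, and loss of their RNA was not tested. Age, time since transplant and batch were not tested here either.

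The higher level of neuronal transcripts at day 30 may reflect neuronal RNA in the sorted material, through debris or uptake, which these data do not tell apart. A lower share of microglia would raise endothelial markers too, whereas their upper quartile was -0.29 against a lower quartile of +0.41 for the neuronal markers. The astrocyte and oligodendrocyte medians were -0.13 and +0.19, and neither list passed. Endothelial, astrocyte and oligodendrocyte markers thus did not all rise together with the neuronal ones. Red cell and dendritic cell markers were higher at day 30, with medians of +0.61 and +0.45 (camera adjusted p = 0.0159 and 0.0423 at the preset correlation). Neither of those lists passed with an estimated correlation (camera adjusted p = 0.315 and 0.245). The endothelial markers may have changed on their own, so they are not a fixed gauge of the share of microglia. Without day 30 replicate 4, the highest library, the neuronal median was +0.50 (camera adjusted p = 0.000173 at the preset correlation). With libraries thinned to equal depth it was +0.69 (camera adjusted p = 2.93e-07 at the preset correlation). Thinning leaves the expected CPM of each gene unchanged, so that fit could hardly move the median and decides little. The higher median thus remained without day 30 replicate 4, while on all 9 libraries the list did not pass with an estimated correlation (adjusted p = 0.187). The sort gate would remove neurons themselves, and Meg3 was the most abundant neuronal marker, at 945, 1792 and 999.8 CPM on days 7, 30 and 90.

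The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. All 10 gave at least the 0 genes of day 30 against day 7 (limma, 939 unadjusted, 0 with edgeR and 34 with DESeq2), the highest other split giving 1. For day 90 against day 7 the real split gave 37 genes and the highest other 25, with day 7 replicates 2 and 3 and day 90 replicate 1 set against the rest, and for day 90 against day 30 the values were 8 and 0. For the F-test, 1 of 100 splits of the 9 libraries, the real one, gave as many as 26 genes, and the highest other gave 13. A chance split is thus unlikely to give that count, but the splits do not separate time from age or batch.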
